A study of Homo sapiens with 24 samples.

How the data were processed

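RNA of blood mononuclear cells kept for 5 days in an endothelial progenitor colony assay was biotin-labelled and hybridised to 1-colour Affymetrix expression arrays, 1 array per culture, per the labels' protocols. The deposited values are array intensities, 1 linear signal per probe set, which the authors made with MAS5, per the submitters' processing notes; the version is not given in the sources used here. The values themselves show that each array had been scaled to the same trimmed mean, with the lowest and highest 2 percent left out, and that no distribution was matched between arrays. That scaling makes a change in a gene relative to the rest of its array. The scanner files and detection calls were not used here. The table held 24 columns, each matched to 1 sample by name, and 0 columns were left unmatched. The signal of a probe set has no counting depth, so the 24 arrays set the precision.

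Of all probe sets, 41091 had 1 gene symbol in the platform annotation, 1801 had several, 11721 had none there and 62 were controls; probe sets with several or no symbols were left out, as were 59 probe sets used only to check for mixed-up samples. Symbols came from GEO's platform annotation, set against a current gene table by gene ID. The remaining probe sets stood for 19740 genes. Signals were taken as log2(signal + 16), so that a change of a dim gene is understated. The probe set with the highest mean over the 24 arrays stood for its gene, and the 9870 genes at or above the median level, a signal of about 326, were tested. Fits used limma 3.58.1 in R 4.3.3, and plots matplotlib 3.10.9 in Python 3.11.15.

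The number in each sample's label marks a person, and these people are called subjects 1 to 12 here, in rising order of that number. The design says that the same people were sampled at both times, so the comparison of time points was paired. It used lmFit with the subject as a block and eBayes with a trend, two-sided, with Benjamini-Hochberg adjustment and a threshold of 0.05. As a check of the pairing, the deviations of a subject's 2 arrays from the group means correlated with a median of 0.50 and a range of -0.07 to 0.70, above 0.1 in 11 of 12 subjects, and 9 of 12 baseline arrays correlated best with the later array of the same subject. Within the hybridisation sets described below, the median was 0.34 and the lowest value -0.19, with 11 of 12 subjects above 0.1. Among the arrays of a set, 10 of 12 baseline arrays correlated best with the later array of the same subject. A check for mixed-up samples found 0 of 12 subjects whose arrays disagreed. No 2 arrays held identical values, and the highest correlation of 2 arrays was 0.947. Cultures at the 2 times come from separate blood samples. The paired p values thus rest on the spread of within-person changes, which joins visits, cultures and arrays. Differences in level between people are taken out by the block.

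Gene lists were written before the data were examined, 12 for cell types (T cell, natural killer and cytotoxic cell, B cell, monocyte, macrophage, dendritic cell, endothelial cell, stem and progenitor cell, platelet and megakaryocyte, erythroid cell, granulocyte, fibroblast) and 14 for functions (angiogenic factors, inflammatory cytokines, interferon response, class II antigen presentation, cell cycle, oxidative phosphorylation, mitochondrial biogenesis, antioxidant defence, glycolysis and hypoxia, cholesterol and lipid, heat shock, immediate early, homing receptors, T cell activation). Some genes stand in 2 lists: CXCL8 and MMP9 are also angiogenic factors, LGMN is also a class II gene and PECAM1 also a homing receptor. The score of a list is the mean log2 value of its tested members, with at least 3 required. It was tested on the 12 within-subject changes with the exact sign-flip test over 4096 patterns, two-sided, with adjustment over the 24 lists, and camera and fry were run beside it. The differences between subjects were tested with the F test of the same limma fit, with the intraclass correlation of the 2 cultures as the size of the effect. Correlations over subjects used 100000 resamples, or every order of the 7 subjects of set I, and were adjusted over 24 lists or over 12 pairs of lists.

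Background was set from 69 probe sets of 50 genes of unrelated tissues such as eye lens, testis, pancreas and kidney. Their 95th percentile in an array was that array's floor, which ranged from 139 to 471 with a median of 252. The median signal of these probe sets was 47.2, and 5 of them lay above the array median in most arrays. The floor thus rests on the brightest few of the 69 and is a strict one. A gene below it can still lie above most of them. A marker was counted as above the floor in most arrays with more than 12 of 24. Levels of different probe sets were not set against each other.

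The hybridisation sets were found after the data were seen, from the probe sets of the bacterial spike-in RNAs bioB and bioC. Their name refers to these controls and states no cause, as no label gives a hybridisation date or lot. Each set holds both time points of its subjects, so the paired comparison was made within sets by design, while differences and correlations between subjects are given pooled and within sets. Exercise by set was tested as an interaction.

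Genes named for the time comparison are the 10 with the smallest p on each side, because fewer than 20 passed, and for each list the 3 members with the smallest p, of which the text gives part. For detection they are up to 4 members of each cell type list with the highest level and a fixed set of well-known markers. For subjects they are the 12 with the highest intraclass correlation over all subjects, leaving out HLA genes, and, added later, the 12 highest within sets. Alternatives were other pseudocounts, filters, normalizations and probe set rules, every probe set on its own, an unpaired fit, each subject left out, the 3' to 5' ratio or cell type scores as covariates, array weights, a robust variance prior, a plain paired test per gene and other floors. Added later were the spike-in level as a covariate, each set alone or centring on the sets, and leaving out the subjects of the 2 arrays with the highest spike-in level.

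The procedures were tested on simulated data. For the comparison after exercise against baseline, values of 9870 genes were drawn 10 times from the measured subject means and residual spreads, with 200 genes changed. At a log2 change of 0.5, 40.8% of the changed genes were recovered, at 1, 87.4%, at 1.5, 97.4% and at 2, 99.8%, and 4.29% of the calls were unchanged genes. These draws are independent between genes, which real arrays are not. The changed genes of a run held all these sizes in equal numbers, so the large changes eased the adjusted threshold for the small ones. With few large changes, as in the measured data, fewer changes of 0.5 would be recovered, and that case was not simulated. With no difference between subjects, the subject test over 9870 genes called 0. Of 100 random lists of 15 genes with no shift, 5% passed an unadjusted 0.05 in the list test. Their centred changes had been given random signs, so a sign-flip test gives about this rate by construction. It shows that the test was coded as meant, and nothing about the measured changes. Of 100 correlation tests on values with no relation, 7% passed an unadjusted 0.05.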

Results

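Gene expression was measured in cells grown for 5 days from the blood mononuclear cells of healthy people, in a colony-forming assay used for endothelial progenitor cells, which are blood-borne cells studied for their part in vessel lining. Each of 12 subjects gave blood at baseline and again after 3 months of exercise. No group without exercise is among the samples, so exercise cannot be told apart from other changes over the 3 months. The 24 cultures, 12 per time point, were each hybridised to 1 array. Median signal per array lay between 114 and 295 on the authors' linear scale, and the number of arrays limits the precision of every value below. The series title asks what the cells of the assay are, and its design asks whether they differ after exercise. A further question, open because each subject was cultured on 2 occasions, is how far the cultures of a person resemble each other.

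The cultures carried broad sets of transcripts of T cells, cytotoxic cells, monocytes, macrophages and dendritic cells, and few of those that mark vascular endothelium. Of 22 T cell markers, 21 lay above the background floor in most of the 24 arrays. All 14 markers of natural killer and cytotoxic cells and all 12 monocyte markers did so too, as did 13 of 18 macrophage, 10 of 14 dendritic cell and 8 of 12 B cell markers. Among endothelial markers the number was 6 of 22, and 10 of the 22 lay above the floor in 0 arrays. Those 10 included CDH5 (VE-cadherin, the adhesion molecule of endothelial junctions), KDR (the main receptor for vascular endothelial growth factor), VWF (von Willebrand factor, stored in endothelial granules) and NOS3 (endothelial nitric oxide synthase). The other 6 were EMCN, ESAM, CLDN5, SOX17, SOX18 and SELE. The mean signal of CDH5 was 81.5 ± 63.7 at baseline (SD, n = 12) and 89.6 ± 95.7 after exercise (SD, n = 12), and that of KDR was 66.0 ± 51.3 and 79.7 ± 81.5 (SD, n = 12 each). VWF stood at 48.3 ± 45.2 at baseline and NOS3 at 63.6 ± 62.5 (SD, n = 12 each). TEK, the angiopoietin receptor, passed the floor in 1 array. PECAM1, an adhesion molecule that leukocytes and platelets also carry, lay above it in 24 of 24 arrays, with a mean signal of 12549 ± 5208 at baseline (SD, n = 12). ENG, the endoglin coreceptor that activated macrophages also make, passed in 24 arrays, ECSCR and FLT1 in 23, VCAM1 in 22 and TIE1 in 21. Each count is that of the brightest probe set of the gene. The lowest other probe set passed in 16 arrays for PECAM1, in 3 for ECSCR, in 1 for TIE1 and in 0 for ENG and FLT1. VCAM1 had 1 probe set.

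**Figure D1:**
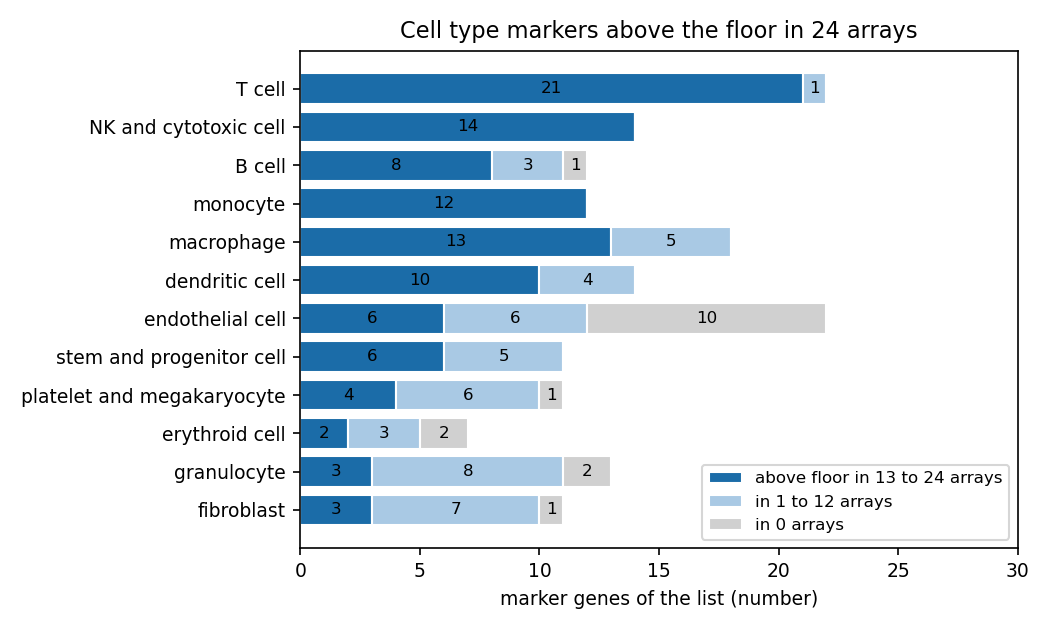
Number of marker genes (x axis) of each cell type list (y axis) by how many of the 24 arrays showed them above the background floor. Dark bars count genes above the floor in 13 to 24 arrays, pale bars those in 1 to 12 and grey bars those in 0; the endothelial list has 10 genes in the grey part, and the T cell list has 21 of its 22 in the dark part.

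Within the T cell list, IL7R (the interleukin 7 receptor), CD3D (a chain of the T cell receptor complex), CD2 and LCK were above the floor in 24 arrays, with mean baseline signals of 46890 ± 14200, 41557 ± 15473, 27755 ± 7319 and 15665 ± 3642 (SD, n = 12 each). CD3E, another chain of the same complex, was read by 1 probe set and passed in 4 arrays only, although CD3D and CD3G passed in all 24. Among cytotoxic genes, the granzymes GZMA and GZMB, perforin (PRF1) and granulysin (GNLY) passed in 24 arrays, with a GZMB signal of 37310 ± 13898 at baseline (SD, n = 12). Of the macrophage genes, MMP9 (a matrix-degrading protease), CHI3L1, SPP1 (osteopontin) and GPNMB passed in 24 arrays. MARCO, a scavenger receptor, passed in 2. The monocyte genes LYZ (lysozyme), S100A8, CLEC7A and MNDA passed in 24 arrays and CD14, the lipopolysaccharide coreceptor, in 14. Of the dendritic cell genes, CCL22 (a chemokine), CD83, LAMP3 and CD209 passed in 24. The B cell genes MS4A1 (CD20), PAX5, FCRLA and CD22 passed in 24 and BLK in 0.

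Of 11 stem and progenitor markers, 6 passed in most arrays, among them MYB and GATA2 in 24 and HLF in 21. CD34 and PROM1 (CD133), the surface antigens most used to define progenitors, passed in 1 and 3 arrays. The platelet list had 4 of 11 markers above the floor in most arrays, with GP1BA in 24, ITGA2B in 18, ITGB3 in 15 and SELP in 13, while PF4 (platelet factor 4) passed in 8. Of 7 erythroid genes, HBB (beta-globin) and HBD passed in 24, AHSP in 12 and SLC4A1 in 7. The granulocyte list had 3 of 13 above the floor in most arrays (MPO in 24, FCGR3B and CSF3R in 22), and CTSG passed in 11. The fibroblast list had 3 of 11, with COL6A3 in 22, PDGFRA in 21, COL1A1 in 17 and THY1 in 10. These counts describe detection against the floor of 50 genes of unrelated tissues and hold no test. The median level of the 19740 genes, a signal of about 326, lay above the median floor of 252, so a gene of any kind often passed. The share of all genes that passed was not computed. The counts of the B cell, stem and progenitor, platelet, erythroid, granulocyte and fibroblast lists thus do not by themselves show that such cells were present. All counts rest on the brightest probe set of each gene, and other probe sets can differ. The lowest other one passed in 24 arrays for IL7R, PRF1, GNLY and GPNMB. It passed in 4 for HBB and HLF, and in 0 for PAX5, CD22, CLEC7A, ITGA2B, ITGB3, PDGFRA and COL1A1. A probe set below the floor does not show that its transcript was absent. The excess of 3' signal in the arrays, given below with their quality, was not set against these counts.

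No gene passed the test for a difference between the time points. In the paired fit with limma, 0 of 9870 genes had an adjusted p under 0.05, and the smallest adjusted p was 0.70. At an unadjusted p under 0.05 there were 693 genes, 7.02% of those tested, of which 320 were higher and 373 lower after exercise. The median change over all genes was 0.002 on the log2 scale and the median standard error 0.14. Among the tested genes 4 had a mean change of 2-fold or more, namely PRG2, HBB, CXCL5 (-1.06 ± 0.35) and RNASE1 (1.09 ± 0.45; SE, n = 12 each), the latter pair chosen after their values were seen. With limma's array weights, which let pairs of arrays count unequally, 634 genes had an adjusted p under 0.05, 297 higher and 337 lower, and 2881 had an unadjusted p under 0.05. A plain paired test per gene gave 0 genes, with 718 at an unadjusted p under 0.05, and limma without subject 5 gave 0, with 1475. Without the replicate block, the unpaired fit gave 0 genes past the threshold and 154 at an unadjusted p under 0.05.

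The genes with the smallest p values, none of which passed, were led by PRG2, which encodes the major basic protein of eosinophil granules. PRG2 was higher after exercise by 1.5 ± 0.31 on the log2 scale (SE, n = 12), with 11 of 12 subjects higher and a limma adjusted p of 0.70. Its baseline mean of 8.13 lay under the filter cut of 8.42 and close to the background floor. It was tested because of its later arrays, and the size of its change is uncertain. The baseline means of SYDE1 (8.39) and LOC102723692 (8.37), named below, also lay under the cut. RIPK3, a kinase of the necroptosis pathway, was higher by 0.51 ± 0.12 (SE, n = 12) and in 12 of 12 subjects, and SNX25 by 0.59 ± 0.15 (SE, n = 12), also in 12 of 12. LOC102723692 was higher in 12 of 12 subjects, SLFN5, AAK1 and SYDE1 in 11, and GUSBP11, STEEP1 and the immunoglobulin light chain gene IGLV1-44 in 10, with changes from 0.41 for SLFN5 to 0.67 for STEEP1. On the other side stood MRPL11, a protein of the mitochondrial ribosome, with a change of -0.41 ± 0.09 (SE, n = 12), higher in 0 of 12 subjects. RAP2C, a small GTPase, changed by -0.30 ± 0.08 (SE, n = 12) and was also higher in 0 of 12. GET4 changed by -0.92 ± 0.23 and IRF5, a transcription factor of inflammatory and interferon signalling, by -0.44 ± 0.11 (SE, n = 12 each). The IRF5 value is that of 1 probe set, and another one ran against it over subject means (r = -0.87, centred on hybridisation sets). EFHD2, E2F6, WDR4, MRPL42, SLC35B1 and HNRNPAB had changes between -0.53 for WDR4 and -0.35 for E2F6. Each of these 20 genes had an adjusted p of 0.70. With array weights, 45 of the 95 genes singled out by the rules for this comparison passed, against 634 of all 9870 tested. The 95 were chosen by their small p in the same arrays, so this is no independent support for them.

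None of the 24 gene lists that could be tested passed the exact sign-flip test of the 12 within-subject changes, the smallest adjusted p being 0.72. The interferon response list came closest. Its score was higher after exercise by 0.24 ± 0.41 on the log2 scale (SD of the change, n = 12), in 9 of 12 subjects and with 19 of its 20 measured members higher (exact p = 0.066, adjusted p = 0.72). ISG15, a ubiquitin-like protein induced by interferon, was higher by 0.42 ± 0.14, OAS3 by 0.42 ± 0.16 and IFI35 by 0.48 ± 0.19 (SE, n = 12 each), with adjusted p of 0.70 for each in the limma fit. The change of the list was 0.20 ± 0.40 in the 7 subjects of 1 hybridisation set and 0.29 ± 0.47 in the 5 of the other (SD). With camera and a preset correlation of 0.01, the interferon list alone had an adjusted p under 0.05, at 5.5e-05. That call was lost with an estimated correlation, where the adjusted p = 0.85, and fry gave an adjusted p of 0.83.

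The mean change of each cell type list was smaller than its SD over the 12 subjects. The T cell list changed by 0.07 ± 0.17 (SD of the change, n = 12) with CD6 higher by 0.34 ± 0.13 (SE), and the cytotoxic list by 0.04 ± 0.32 with GNLY higher by 0.29 ± 0.15. The changes were 0.16 ± 0.38 for B cells, 0.09 ± 0.80 for monocytes, 0.16 ± 0.76 for macrophages, 0.09 ± 0.41 for dendritic cells and 0.12 ± 0.35 for the 6 measured endothelial genes (SD, n = 12 each). They were 0.24 ± 0.83 for stem and progenitor genes, 0.10 ± 0.49 for granulocyte genes and 0.38 ± 0.75 for the 3 measured fibroblast genes (SD, n = 12 each). Leaving out 1 subject moved the mean by over 1.5 times in 23 of the 24 lists of all kinds, the exception being interferon response, which ranged from 0.17 to 0.28. The macrophage change was 0.02 without subject 4 and 0.25 without subject 5 or 11, the B cell change 0.10 without subject 6, the fibroblast change 0.22 without subject 11, and the stem and progenitor change 0.11 without subject 11 and 0.10 without subject 12. The mean turned negative for monocytes without subject 1 (-0.02) and for dendritic cells without subject 11. Adjusted over the list alone, 1 member passed in each of 3 lists, and 0 of these members passed over all genes. They were the chemokine CCL22 in the dendritic cell list, at 0.67 ± 0.21 (SE, n = 12, adjusted p = 0.042 over its list and 0.70 in the limma fit of all genes), COL1A1 (type I collagen) in the fibroblast list, at 0.69 ± 0.24 (SE, n = 12, adjusted p = 0.030 over its list) though above the floor in only 7 of 12 baseline and 10 of 12 later arrays, and JUN, a subunit of the AP-1 transcription factor, in the immediate early list. JUN changed by -0.38 ± 0.11 (SE, n = 12, adjusted p = 0.045 over its list) and was higher in 1 of 12 subjects. Of the other cell type members with the smallest p, APOC1 of the macrophage list was higher by 0.66 ± 0.25, LYZ by 0.45 ± 0.18 and KIT, the stem cell factor receptor, by 0.62 ± 0.28, though above the floor in 13 of 24 arrays, while CD209 changed by -0.33 ± 0.14 (SE, n = 12 each, adjusted p of 0.70 each in the limma fit). The platelet and erythroid lists had 2 measured members each and were not tested. HBB was higher by 1.0 ± 0.46 and ITGA2B by 0.75 ± 0.32 (SE, n = 12 each), with limma adjusted p of 0.71 and 0.70. The baseline means of COL1A1 (8.16), KIT (8.19) and ITGA2B (8.22) lay under the filter cut of 8.42. These genes were tested because of their later arrays, and the sizes of their changes are uncertain. The adjustment over the fibroblast list covered only its 3 measured genes.

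Signalling and metabolic lists did not pass either. The inflammatory cytokine list changed by -0.18 ± 0.68 (SD of the change, n = 12), with 13 of 16 members lower, IL1B (interleukin 1 beta) at -0.47 ± 0.16 and CCL20 at -0.46 ± 0.24 (SE), and the list changed by -0.08 without subject 11 and -0.06 without subject 12. The immediate early list changed by -0.17 ± 0.48 (SD), or -0.08 without subject 11, with KLF4 at -0.41 ± 0.14 (SE). Changes were 0.10 ± 0.98 for the cell cycle list, 0.07 ± 0.31 for angiogenic factors, 0.05 ± 0.32 for class II antigen presentation, 0.04 ± 0.20 for homing receptors and -0.05 ± 0.45 for T cell activation (SD, n = 12 each). The cell cycle list had 20 of 23 members higher on average but was higher in 4 of 12 subjects only. Its positive mean came from subjects 11 and 12, whose baseline scores of 9.98 and 10.68 were the lowest of the 12, and it was -0.04 without subject 11 and -0.10 without subject 12. Among metabolic lists, oxidative phosphorylation changed by 0.05 ± 0.15, mitochondrial biogenesis by -0.05 ± 0.15, antioxidant defence by 0.02 ± 0.17, glycolysis and hypoxia by 0.05 ± 0.19, cholesterol and lipid by -0.01 ± 0.18 and heat shock by 0.06 ± 0.28 (SD, n = 12 each). The direction of the mean also turned for homing receptors without subject 3, for T cell activation without subject 4, and for cholesterol and lipid without subject 1, 6 or 8. SOD2, the mitochondrial superoxide dismutase, was higher by 0.74 ± 0.26, COX5B (a subunit of cytochrome c oxidase) by 0.29 ± 0.09 and TNFRSF9 (4-1BB, a T cell costimulator) by 0.40 ± 0.15, and ITGB1 (integrin beta 1) changed by -0.38 ± 0.12 and CD69 by -0.54 ± 0.22 (SE, n = 12 each, limma adjusted p of 0.70 each). The 95% interval of the mean change ran from -0.03 to 0.18 for the T cell list and from -0.05 to 0.15 for oxidative phosphorylation, and from -0.52 to 0.72 for the cell cycle list.

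**Figure D2:**
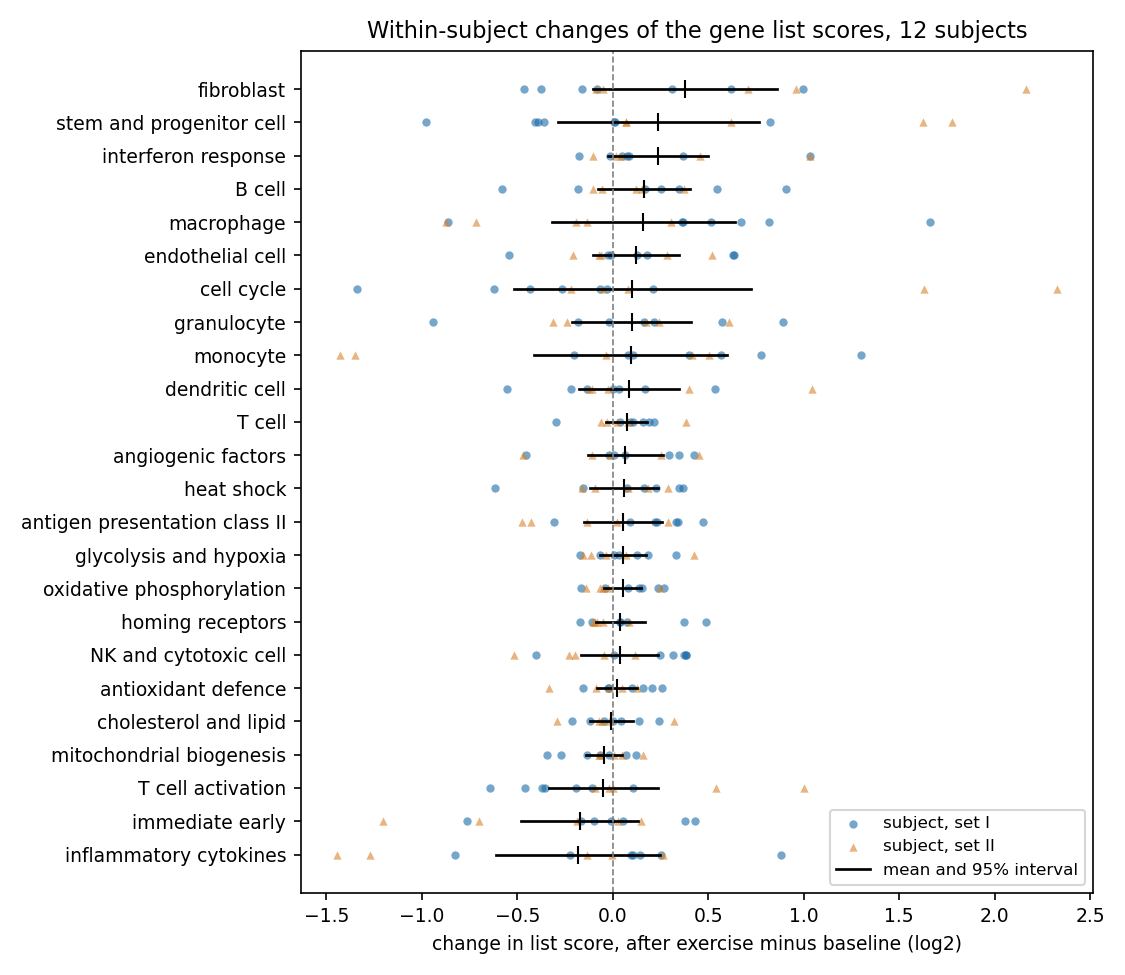
Change of each gene list score from baseline to after exercise (x axis, log2) for the 24 lists tested (y axis). Coloured marks are the 12 subjects by hybridisation set, black lines the mean with its 95% interval; the interferon response list has a mean of 0.24, and points of the T cell list lie closer together than those of the cell cycle list.

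Subjects differed from each other in many genes. With all 12 subjects, 4601 of 9870 genes (46.6%) had an adjusted p under 0.05 in the limma F test between subjects. The arrays fell into 2 sets by their bacterial spike-in controls, 7 subjects with 14 arrays in set I and 5 subjects with 10 arrays in set II, and both arrays of a subject lay in the same set. Set and subject can thus not be separated over all subjects. Tested within these sets, 1676 genes (17.0%) passed, all of them also among the 4601. No label says whether the 2 samples of a subject were processed together. If they were, testing within sets does not take out what such a pair shared. The counts, intraclass correlations and correlations between visits given here cannot tell that apart from the person. The genes with the highest intraclass correlation within sets, where 1 means that both cultures of a person gave the same value relative to other people, included SLC5A3 (a myo-inositol transporter, 0.974), IMMP1L (a mitochondrial inner membrane peptidase, 0.967), IRF5 (0.964), CHURC1 (0.956) and ZNF232-AS1 (0.953). TNFRSF10A, a receptor for the death ligand TRAIL, had 0.942 and LAMP2, a lysosomal membrane protein, 0.941. ITGB3BP, CD8A (the coreceptor of cytotoxic T cells), ERAP2 (an aminopeptidase that trims peptides for class I molecules), PSD3 and PAX8-AS1 lay between 0.938 for ITGB3BP and 0.933 for PAX8-AS1. The subject means of ERAP2 had an SD of 1.37 on the log2 scale, against 0.35 within subjects, and those of IRF5 an SD of 1.29 against 0.26. OPTN, LRRC59, TSPAN13, TMEM69 and CDC16 ranked among the highest 12 over all subjects, at 0.949 to 0.960, but within sets the intraclass correlation of CDC16 was 0.688 and that of OPTN 0.784, and neither passed there (limma adjusted p of 0.052 and 0.19). Within sets and without subject 8, the count of genes was 822, and it was 1004 without subject 3 and 1055 without subject 2.

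**Figure D3:**
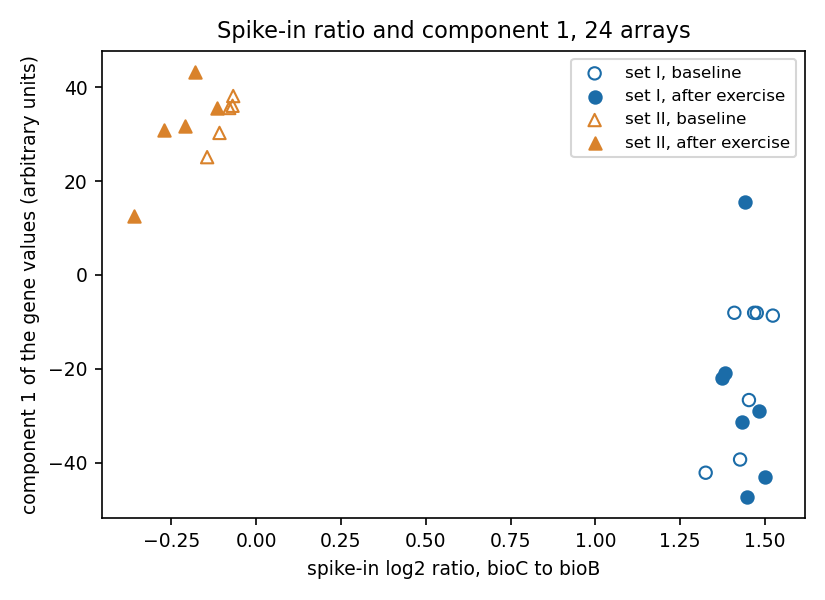
Log2 ratio of the bacterial spike-in controls bioC and bioB (x axis) and first principal component of the 9870 genes (y axis) for the 24 arrays, by hybridisation set and time point. The 14 arrays of set I lie at 1.33 or above on the x axis and the 10 of set II at -0.07 or below; the component held 27.7% of the variance.

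Set against the 17.0% of all tested genes that passed within the sets, the share of list members that passed was not tested for enrichment. Of the measured members, 9 of 13 cytotoxic, 7 of 9 dendritic cell, 12 of 20 interferon response, 11 of 21 T cell, 7 of 13 macrophage, 6 of 11 class II and 6 of 11 monocyte genes passed. Adjusted over the list alone, the T cell count was 14, the cytotoxic count 10 and the interferon count 14. Of the cell cycle list 0 of 23 members passed within sets, and of the oxidative phosphorylation list 1 of 24, against 16 of 24 over all subjects. Of the cholesterol and lipid list 4 of 11 passed, and of the B cell list 4 of 7. The remaining lists had between 0 members (stem and progenitor, 5 measured; fibroblast, 3 measured) and 6 members (antioxidant defence, 19 measured; inflammatory cytokines, 16 measured) past the threshold within sets.

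The list scores of a person at baseline were set against those 3 months later. Over 12 subjects, 8 of 24 lists passed the permutation test. T cell activation had r = 0.88 (rho = 0.84, p = 0.0011 for rho, adjusted p = 0.0029 for r), the cytotoxic list r = 0.81 (rho = 0.84, p = 0.0014 for rho, adjusted p = 0.015) and the T cell list r = 0.81 (rho = 0.63, p = 0.033 for rho, adjusted p = 0.022). The B cell list had r = 0.69, class II antigen presentation 0.69, glycolysis and hypoxia 0.69, interferon response 0.67 and oxidative phosphorylation 0.67, each with an adjusted p of 0.0498. With scores centred on the hybridisation sets, 4 lists passed, namely the cytotoxic list (r = 0.87, adjusted p = 0.014), T cell activation (r = 0.83, adjusted p = 0.014), class II (r = 0.74, adjusted p = 0.016) and T cell (r = 0.80, adjusted p = 0.044), while oxidative phosphorylation had r = 0.20. In set I alone (7 subjects, exact permutation test), r was 0.81 for the monocyte list (p = 0.0063), 0.86 for the cytotoxic list (p = 0.012), 0.86 for T cell (p = 0.017), 0.79 for class II (p = 0.019), 0.79 for glycolysis and hypoxia (p = 0.031) and 0.78 for T cell activation (p = 0.044), none with an adjusted p under 0.05, and set II, with 5 subjects, was below the size at which correlations are given here. Without the 2 subjects farthest from the median at baseline, r was 0.79 for the cytotoxic list (permutation p = 0.00785), 0.70 for T cell activation (permutation p = 0.025), 0.51 for the T cell list (permutation p = 0.13) and 0.52 for class II (permutation p = 0.12), so that the latter 2 did not pass with the remaining subjects, fewer in number and narrower in range. It was 0.68 for interferon response (permutation p = 0.032), 0.66 for B cells (permutation p = 0.040), 0.63 for glycolysis and hypoxia (permutation p = 0.053) and 0.56 for oxidative phosphorylation (permutation p = 0.093). Of lists that had not passed, r without those subjects was 0.83 for the monocyte list (permutation p = 0.00061), 0.74 for inflammatory cytokines (permutation p = 0.014) and 0.69 for dendritic cells (permutation p = 0.028). Centred on sets, these were 0.43 (permutation p = 0.21), 0.23 (permutation p = 0.51) and 0.78 (permutation p = 0.0071). Centred on sets, the B cell list had r = 0.65 (adjusted p = 0.17), and 0.085 without its 2 farthest subjects (permutation p = 0.82); not centred, it fell to 0.42 without subject 2 (adjusted p = 0.34). Without subject 3, whose removal changed it most, the T cell list had r = 0.58 (adjusted p = 0.14), and without subject 4 its adjusted p was 0.058. The number of lists past the threshold was 2 without subject 4, 3 without any 1 of subjects 1, 2, 3, 7, 8, 9 and 10, 4 without subject 6 and 5 without subject 12. The cell cycle list had r = 0.16 and the macrophage list 0.38, with adjusted p of 0.75 and 0.31.

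**Figure D4:**
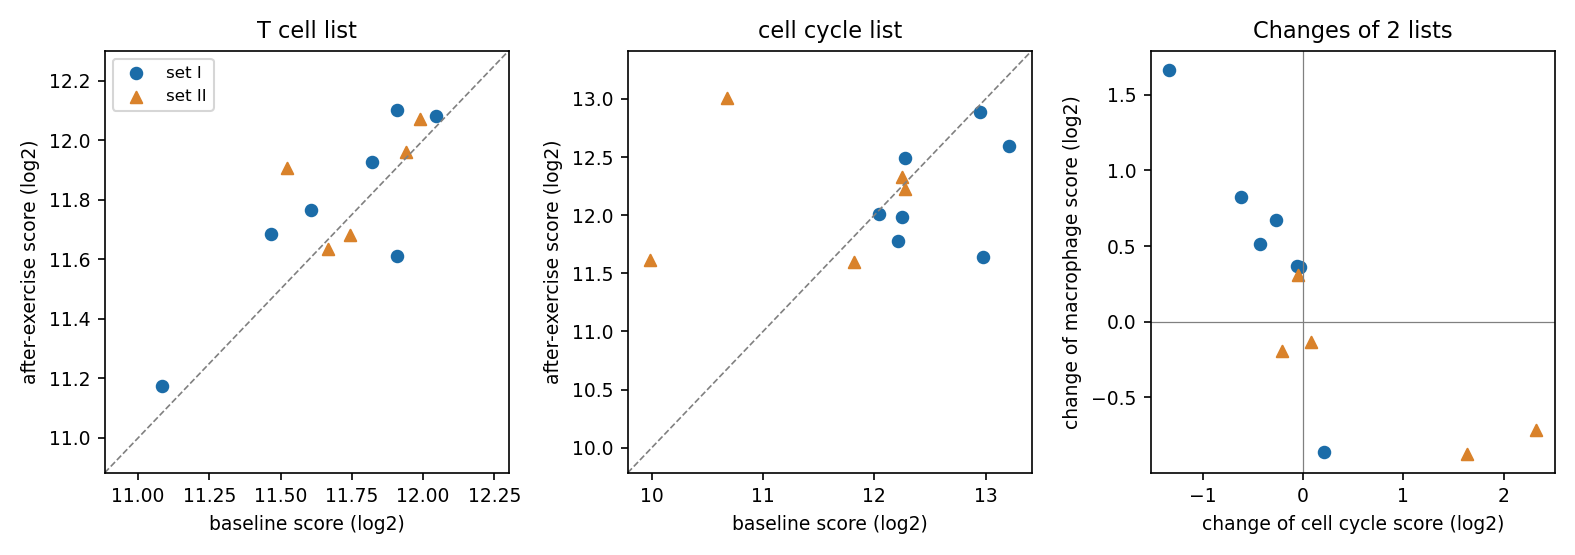
Scores of the T cell list and of the cell cycle list at baseline (x axis, log2) and after exercise (y axis, log2), and the change of the macrophage score (y axis) against that of the cell cycle score (x axis). Each mark is 1 of 12 subjects, dashed lines mark equal scores; r was 0.81, 0.16 and -0.82 from left to right.

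Cell cycle and macrophage genes moved in opposite directions. Of 12 pairs of lists fixed in advance and computed, this was the only one that passed over subject means, with r = -0.81 (rho = -0.68, p = 0.019 for rho, adjusted p = 0.011 for r), and the only one over within-subject changes, with r = -0.82 (rho = -0.90, p = 0.00015 for rho, adjusted p = 0.0055). The cell cycle list holds genes such as TOP2A and MKI67, which dividing cells make, and the macrophage list genes such as SPP1 and APOC1. Centred on the hybridisation sets, r was -0.81 for subject means (adjusted p = 0.060, no longer past the threshold) and -0.73 for changes (adjusted p = 0.011). In set I alone (7 subjects, exact permutation test), r was -0.90 for subject means (p = 0.0034) and -0.90 for changes (p = 0.0081). Without the 2 subjects farthest from the median cell cycle value, r was -0.62 for subject means (permutation p = 0.052) and -0.88 for changes (permutation p = 0.00047). The relation of subject means lost its call without subject 2 (r = -0.77, adjusted p = 0.061) and without subject 11 (r = -0.69, adjusted p = 0.12). Over changes, the T cell list also passed with the cytotoxic list (r = 0.75, adjusted p = 0.021) and the B cell list (r = 0.76, adjusted p = 0.032) without subject 9, and the endothelial list with the macrophage list (r = 0.76, adjusted p = 0.045) without subject 11. With a stricter filter on dim genes, the T cell and cytotoxic lists had r = -0.19 over changes, against 0.57 for all 12 subjects and the filter used throughout. The T cell list with the macrophage list gave r = -0.39 over subject means and 0.37 over changes, and with the endothelial list -0.41 and 0.33, with adjusted p of 0.56 and 0.47 for the first pair and 0.56 and 0.50 for the second. The other pairs had r between -0.33 and 0.62, and none passed.

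None of 8 measures of array quality differed between the time points after adjustment, 4 of them fixed in advance and the rest added. The log2 ratio of 3' to 5' signal was 4.36 ± 0.38 at baseline and 4.40 ± 0.84 after exercise for GAPDH (SD, n = 12 each, exact p = 0.86), and 6.84 ± 0.36 and 7.01 ± 1.17 for ACTB (SD, n = 12 each, exact p = 0.69). Over single arrays this ratio ran from 2.75 to 5.56 for GAPDH and from 5.94 to 10.24 for ACTB. The 3' signal of both genes was thus the higher one in every array. Whether this lowered probe sets away from the 3' end, and so the marker counts against the floor, was not tested. The median signal was 166 ± 34 and 196 ± 53 (SD, n = 12 each, exact p = 0.069), and the score of the unrelated tissue genes 6.09 ± 0.28 and 6.29 ± 0.38 (SD, n = 12 each, exact p = 0.14). The arrays taken after exercise correlated less with the other arrays, at a mean of 0.898 ± 0.017 against 0.909 ± 0.008 (SD, n = 12 each, exact p = 0.038, adjusted p = 0.14 over 8 measures). The level of the bacterial spike-in controls was 13.55 ± 0.42 at baseline and 14.22 ± 1.07 after exercise on the log2 scale (SD, n = 12 each), higher in 8 of 12 subjects (exact p = 0.065), and the exact p for the bioC to bioB ratio was 0.070 and that for the first principal component 0.48. The array of subject 8 after exercise stood apart, with a mean correlation of 0.853, a log2 3' to 5' ratio of 10.24 for ACTB and the highest spike-in level, 16.37; that of subject 10 after exercise had 15.83.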

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

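The tests in this part were chosen only after the split of the arrays was seen. Bacterial RNAs added to each sample before hybridisation, which are no measurement of the cultures, divided the arrays without overlap. The log2 ratio of bioC to bioB had a mean of 1.44 ± 0.05 in the 14 arrays of 7 subjects (SD) and -0.16 ± 0.10 in the 10 arrays of 5 subjects (SD), a difference of 1.60, with a lowest value of 1.33 in set I and a highest of -0.07 in set II. Both arrays of each subject lay in 1 set. Between the sets 3263 of 9870 genes differed in limma with subjects as a random block (adjusted p under 0.05), 1576 higher and 1687 lower in set II. Of the list scores, oxidative phosphorylation alone differed after adjustment, higher in set II by 0.29 (exact p = 0.0013, adjusted p = 0.030).

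Chance can be excluded for this gene count, since on subject means the real division gave 3141 genes, and 1 of 100 divisions of the subjects into 7 and 5, the real one, reached that number, with a highest count of 1 gene among the others. The ratio of cre to bioD, 2 controls not used to define the sets, also differed, by -0.23 with a spread of 0.08 (exact p = 0.0013), and by -0.21 without subject 8 (exact p = 0.0030). Being a ratio of added RNAs, it does not show what moved the genes of the cultures. A difference in reagents or hybridisation is a candidate explanation of the gene count. RNA degradation cannot be told apart from it: the log2 3' to 5' ratio of ACTB was higher in set II by 0.70, with a spread of 0.59 (exact p = 0.051), but by 0.37 without subject 8, whose array after exercise had the highest ratio, with a spread of 0.36 (exact p = 0.15). Cell makeup stays open as well, because different people make up the sets; the largest difference among cell type lists was 0.52, for stem and progenitor genes, none passed (smallest adjusted p = 0.16), and the called genes had a median size of 0.78. The sets follow the order of the subjects' label numbers, with those called 1 to 7 here in set I and 8 to 12 in set II. Other differences between these people thus stay open and untested.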

How the results depend on the processing

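Settings chosen after the data were seen were the spike-in covariate, the hybridisation sets, the removal of the subjects of the 2 arrays with the highest spike-in level (subjects 8 and 10), and leaving out single subjects for everything but the time comparison. The count of 0 genes after exercise held under all other settings run, the paired and unpaired fits included, but was 634 with array weights; the unadjusted count was 477 to 1475 with single subjects left out, the highest without subject 5. The unpaired test without the replicate block changed no call, with 0 lists past the threshold. The count of 0 lists became 1 with camera's preset correlation. Of single genes and lists named for the time comparison, 53 and 37 values changed sign in some setting, none of them past a threshold, and 2597 and 557 kept direction and call.

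The 4601 genes that differed between subjects became 3037 with a stricter filter on dim genes and 7395 for every probe set, where fewer genes or more probe sets were tested, 2490 with the mean of probe sets, and 1676 within sets; single removals gave 3860 to 5344. The 1676 became 778 with the mean of probe sets, 628 without subjects 8 and 10, and 822 to 2256 with single removals. The 8 repeatable lists became 3 with a pseudocount of 1, 4 with the stricter filter, 4 with median centring, 5 with the mean of probe sets, 4 centred on sets, 3 without subjects 8 and 10, and 2 to 8 with single removals. Pseudocount 1 left 5 of them just short of a call, at adjusted p of 0.050. The relation of subject means became 0 centred on sets and 0 to 1 with single removals; that of changes stayed at 1 except for 3 without subject 9 and 2 without subject 11, a range of 1 to 3. Markers above the floor numbered 102, with 91 under the highest floor tried, or 61.1% of genes against 43.9% of all probe sets. Apart from fewer subjects, genes or probe sets, the cause was not tested. Dim genes are limited by signal over background: 10 endothelial markers lay below the floor in 24 arrays.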

Other observations

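The array weights, quantile normalization and the pairs of the T cell list with the macrophage and cell cycle lists were planned. The other tests in this part were chosen only after the results they bear on were seen. So was the use of those pairs to weigh the opposed changes. Of 17 genes named for high intraclass correlation, 12 had another measured probe set, 20 in all, and 15 of these 20 had an intraclass correlation within sets over 0.5, which does not show that they follow the named probe set. The other 5 genes had no second measured probe set. For ERAP2 the 2 other probe sets had 0.959 and 0.910 and followed the named one over subject means with r = 0.99 and 0.94, centred on sets. IRF5 went the other way: its second probe set had an intraclass correlation of 0.933, and its subject means ran against those of the named probe set with r = -0.87. 1 probe set of CHURC1 (r = -0.44) and 1 of CDC16 (r = -0.30) also had a negative r, and those of OPTN and PAX8-AS1 had r = 0.19 and 0.24. These r values were not tested.

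The change from baseline to after exercise did not pass a test of a difference between the hybridisation sets, with 0 genes past the threshold in limma, a smallest adjusted p of 0.11 and 833 genes at an unadjusted p under 0.05. On within-subject changes that count was 783, and 17 of 100 divisions of the subjects into 7 and 5 gave as many, the highest other being 2203, so chance cannot be excluded. Of 24 lists, 0 differed after adjustment, and 4 had an exact p under 0.05 for the difference between sets, each of the smallest 3 with an adjusted p of 0.22. T cell activation changed by -0.29 ± 0.25 in set I and 0.29 ± 0.47 in set II (SD, exact p = 0.015), and stem and progenitor genes by -0.18 in set I and 0.83 in set II (exact p = 0.023). The cell cycle list changed by -0.36 ± 0.51 in set I and 0.75 ± 1.15 in set II (SD, exact p = 0.028), and the cytotoxic list by 0.19 in set I and -0.18 in set II (exact p = 0.048, adjusted p = 0.28).

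Swapping the 2 arrays of random subjects keeps every pair. The real order gave 693 genes at an unadjusted p under 0.05, and 21 of 100 splits, the real one included, gave as many, with a highest other of 3157. With array weights the real order gave 634 genes past the threshold, and 9 of 100 splits gave as many, with a highest other of 2812, so chance can be excluded for neither count. Of the 99 other splits, 15 called at least 1 gene with array weights and 4 without. Counts several times the real one can come from a structure of the samples or from genes that vary together, and neither was tested. The weighting itself also stays open as a source of the 15. The weights ran from 0.33 for the arrays of subject 5 to 2.63 for those of subject 7.

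Cell cycle and macrophage genes had opposed changes. A scaling factor shared by all genes of an array moves lists the same way. It does not account for the opposed changes, as their r was -0.80 after quantile normalization (permutation p = 0.0012). Holding every array to the same trimmed mean can also set lists against each other. Quantile normalization keeps such a constraint, so this test cannot decide on it. The hybridisation sets do not account for the opposed changes, with r = -0.73 centred on the sets (permutation p = 0.0009). A candidate explanation is that cultures with more macrophages hold fewer dividing lymphocytes. The T cell and macrophage changes had r = 0.37 (permutation p = 0.24), which gives it no support and, with 12 subjects, does not exclude it. Over subject means the same pair had r = -0.39 (permutation p = 0.22), the direction this explanation predicts, without passing. The T cell list does not single out dividing cells. The cell cycle and T cell lists had r = -0.13 over changes (permutation p = 0.66) and 0.34 over subject means (permutation p = 0.26). Centred on sets, their subject means had r = 0.52 (permutation p = 0.052) and rho = 0.71 (permutation p = 0.015, unadjusted). No r of this pair passed, and its 2 directions do not decide the question. Exercise as a source stays open, and neither list changed on average past its threshold. In the exact sign-flip test the adjusted p was 0.79 for the cell cycle list and 0.72 for the macrophage list.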
